A study of Mus musculus with 8 samples.

How the data were processed

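RNA was measured by bulk sequencing of the femoral cortical shaft of mice at postnatal day 7, in 4 libraries from mice homozygous for a floxed Slc26a2 allele (CKO) and 4 libraries from mice heterozygous for it (control). All carried the Col2.3kb-Cre driver. Group and replicate number were taken from the sample titles. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made with the NEBNext Ultra RNA kit, and no strand setting is given in the sources used here. The tools listed in the submitters' processing notes, without role or order, are CASAVA 1.8, fastp, HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 1.20.0, with the GRCm38 mouse genome. The gene annotation and the rule by which genes entered the table are not given in the sources used here.

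The data are 1 table of 14457 genes. Per the file headers, it holds FPKM (fragments per kilobase of transcript scaled to 1e6 mapped fragments) for each of the 8 libraries, as computed by the authors. It also holds the authors' p-value for each gene, and the authors' log2 fold change, which are named as the authors' deposited table wherever they are used. The log2 fold change had the same sign as the CKO over control ratio of mean FPKM for 13989 genes. FPKM is scaled to library size and transcript length, so sequencing depth is unknown, and no counting interval or detection floor was given. Low FPKM values were tested for steps of whole reads. In the library with the clearest steps, the mean distance from a whole number was 0.218, against 0.25 by chance, so reads were not recovered and no count model was run. The design written beforehand named a count test for the case of raw counts, and the test it named for FPKM was used.

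Gene identifiers of 13477 genes were found in GENCODE M21, an annotation of the same GRCm38 build, which gave coordinates, gene types and the length of the longest protein-coding transcript. Another 969 rows were assembled genes with no annotated identifier. No pair of libraries held identical values, and the Pearson correlation between libraries lay between 0.854 and 0.984.

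For the comparison of CKO with control, genes with at least 1 FPKM in at least 4 of the 8 libraries were kept (12748 genes, with 1709 left out). log2(FPKM + 1) was fitted with limma 3.58.1 in R 4.3.3 (eBayes with an intensity trend, genotype as the only term), and p-values were adjusted by the Benjamini-Hochberg method over the genes kept, with a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values. The values of Slc26a2 were also compared by an exact two-sided permutation test over the 70 assignments of 4 libraries against 4. A total of 33 gene lists were tested with camera from limma (inter-gene correlation preset to 0.01, Benjamini-Hochberg over the lists). They were run again with the correlation estimated from the data and with fry, a rotation test. The lists cover sulfate handling, glycosaminoglycans, proteoglycans, bone cell stages, mechanosensing, collagen, proteases, signalling, stress, metabolism, sex-linked genes and markers of other cell types of the shaft. Within each list, p-values were adjusted over all genes tested and again over the list alone.

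Named genes followed a rule. They are Slc26a2, then the 10 genes with the largest increase and the 10 with the largest decrease among protein-coding genes that passed the threshold, had groups that did not overlap, had at least 5 FPKM on average in the higher group and carried no placeholder symbol. In each list, up to 3 members with the smallest adjusted p past the threshold were added or, where none passed, the 2 with the highest mean. The values of 1 gene that the rule admits are not reported here. Genes named outside the rule are said to have been chosen after their values were seen. The lists, the rule, the tests and the other settings listed below as planned were fixed before the data were examined.

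The fit was tested on simulated data built on the same 12748 genes and 4 against 4 libraries, with 200 changed genes in each of 20 simulated sets. It recovered 31.8% of genes changed by 1 on the log2 scale and 84.2% of those changed by 2, and 5.01% of its calls were false. A planted list shift ranked 1 of the lists, and 0 other lists were called. The simulated genes varied independently of each other, unlike those measured. The simulation therefore does not test the false calls among genes, or of lists, whose members vary together.

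Other settings, planned beforehand, were median-of-ratios scaling, quantile normalization, no filter, a filter at 5 FPKM, pseudocounts of 0.1 and 0.01, array weights, robust eBayes, replicate number as a block, covariates for Y-linked, skeletal muscle and marrow-lineage expression, and leaving out each library in turn. Added after the data were seen were rescaling to equal FPKM totals, removal of a loess trend (span 0.4) against transcript length, and fits within the libraries with and without Y-linked expression. All 8 libraries were analysed. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.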

Results

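SLC26A2 is a sulfate transporter of the plasma membrane, and sulfate taken up by cells is needed to sulfate the glycosaminoglycan chains of matrix proteoglycans. The study asked which molecular changes accompany the disturbed maturation of osteoblasts that lack it. Bulk RNA was sequenced from the femoral cortical shaft of mice at postnatal day 7. The Col2.3kb-Cre driver, which uses a fragment of the type I collagen promoter active in osteoblasts, was combined with homozygous (CKO, 4 libraries) or heterozygous (control, 4 libraries) floxed Slc26a2. The labels give a replicate number but do not say that each library came from a separate mouse, so p-values measure only the spread between these samples.

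The dissected shaft held cells beyond osteoblasts, and the libraries differed in more than genotype. FPKM summed to 352283 to 379669 in the control libraries and to 431612 to 598419 in the CKO libraries, so the totals did not overlap between genotypes. The 2 highest sums belonged to CKO replicates 3 and 4. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were listed at 0 FPKM in control replicate 1 and CKO replicates 1 to 3, and were above 0 in control replicates 2 to 4 and CKO replicate 4. In CKO replicate 4 they were all lower than in those controls. Kdm5d was at 0.296 FPKM against 2.57 to 3.51 FPKM, and Uty at 0.453 FPKM against 2.74 to 3.88 FPKM. The Y-linked covariate is their mean log2(FPKM + 1), at 1.81 in CKO replicate 4 and 2.97 to 3.22 in control replicates 2 to 4. It places CKO replicate 4 between the classes and is not a clean term for sex. CKO replicate 4 stood apart. It had 155 genes listed at 0 against 9 to 31 in the other CKO libraries, mitochondrially encoded genes made up 2.92% of its FPKM against 9.13% to 14.8% elsewhere, hemoglobin genes 12.3% against 0.997% to 6.25%, and its correlation with the mean of its group was 0.902. The mean of the skeletal muscle list ranged from 1.31 to 6.43 log2 units and overlapped between genotypes.

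Slc26a2 (ENSMUSG00000034320, GRCm38 chromosome 18, 61192919 to 61211612) was lower in CKO, with every CKO library below every control library. Control replicates 1 to 4 had 4.37, 7.49, 4.85 and 4.85 FPKM, and CKO replicates 1 to 4 had 2.93, 2.08, 0.706 and 0.829 FPKM. The means were 5.39 ± 1.42 FPKM in control and 1.64 ± 1.06 FPKM in CKO (SD, n = 4 each), a level 69.6% lower (exact two-sided permutation p = 0.0286, the smallest that 70 assignments can give). The limma log2 fold change was -1.34 with an SE of 0.30 and an adjusted p of 0.0412. Without control replicate 2, 3 or 4 the limma adjusted p was 0.139, 0.165 and 0.112, and without CKO replicate 1, 2 or 3 it was 0.0577, 0.0551 and 0.102. The log2 fold change over all fits that left out 1 library lay between -1.56 and -1.16. Within the libraries lacking Y-linked expression the value was 4.37 FPKM in control and a mean of 1.91 FPKM in CKO, and within those with it a mean of 5.73 FPKM in control and 0.829 FPKM in CKO.

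**Figure D1:**
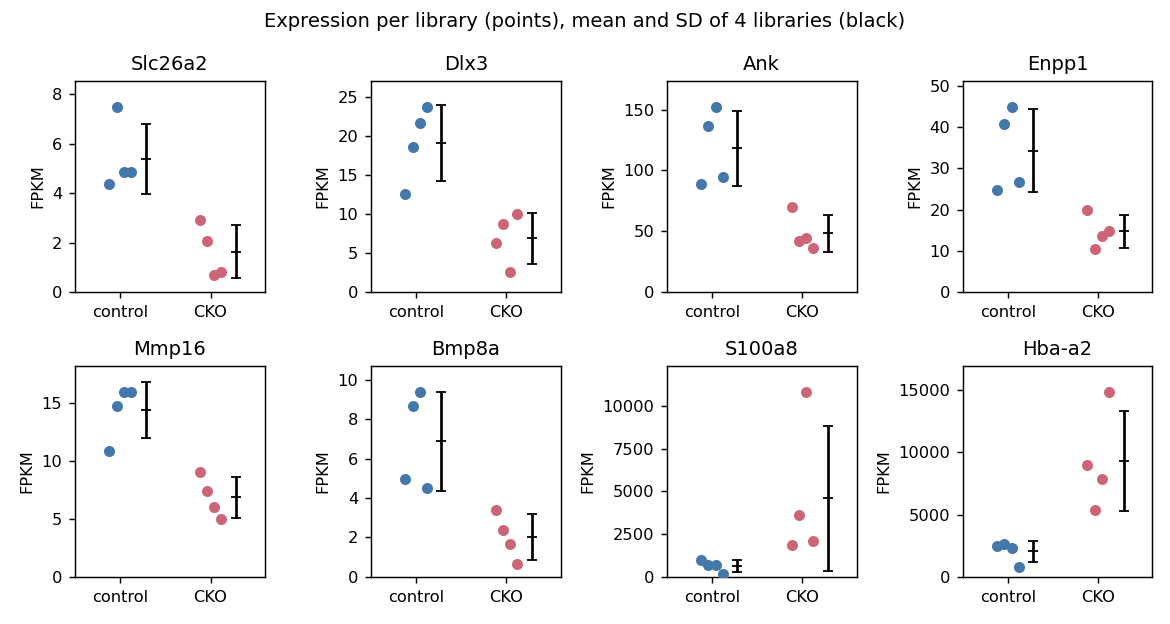
FPKM of 8 named genes in each library (points, control blue, CKO red), with the mean and SD of 4 libraries in black. Slc26a2, Dlx3, Ank, Enpp1, Mmp16 and Bmp8a were lower and S100a8 and Hba-a2 were higher in every CKO library than in any control library.

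Across the transcriptome, 578 of 12748 genes differed between CKO and control by limma with Benjamini-Hochberg adjustment at 0.05. All 578 had an adjusted p between 0.0388 and 0.0499, just under the threshold. Of these, 495 were higher and 83 were lower in CKO (85.6% higher), and 452 differed at least 2-fold. In 572 of them the groups did not overlap, as in 18.7% of all tested genes, where chance gives 2.86%. Among genes admitted by the naming rule, the largest increases were in stefins, cysteine protease inhibitors of myeloid cells, and in other genes of granulocytes. Stfa1 went from 198 ± 135 to 2090 ± 2365 FPKM (SD, n = 4), a log2 fold change of 3.11. Its CKO values were 5614 FPKM in replicate 3 and 533 to 1168 FPKM in the other libraries. Stfa3, Cstdc5, Cstdc4, Wfdc21, S100a9, S100a8, Stfa2l1, Csta2 and Camp followed with log2 fold changes between 2.55 and 3.09. The stefin genes are near-identical copies whose reads the authors' counting could split, so the value of each is uncertain. The largest decreases were in Car12 (log2 fold change -1.64), a membrane carbonic anhydrase, Fat1 (-1.64), an atypical cadherin, Adgrd1 (-1.42), an adhesion receptor, Sdk2 (-1.35), a cell adhesion molecule, and the receptors Notch3 (-1.52), Lrp4 (-1.45) and Unc5c (-1.36). The homeobox gene Dlx3 (-1.44), Bmp8a (-1.41) and Slc26a2 itself completed the 10 largest decreases.

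These counts rested on single libraries and on the scaling. Without control replicate 2, 3 or 4, limma called 0 genes at the adjusted threshold, with 2297, 2103 and 2479 genes at an unadjusted p under 0.05, and without CKO replicate 1, 2 or 3 it called 0, with 3105, 3234 and 2632, against 3228 with all libraries. In the order given, the lowest adjusted p by limma was 0.134, 0.165, 0.111, 0.0577, 0.0501 and 0.0924. Without control replicate 1 limma called 815 genes, and without CKO replicate 4 it called 1885. In each of these 8 fits all 578 genes had the same sign and an unadjusted p under 0.05. The genes were selected from these same libraries, so this is not independent support. Quantile normalization called 358 genes, 137 higher and 221 lower (38.3% higher), and median-of-ratios scaling called 0, with 3397 at an unadjusted p under 0.05. With equal FPKM totals, added after the data were seen, limma called 0 genes. At an unadjusted p under 0.05 it then gave 612 genes higher and 3322 lower in CKO, against 2023 and 1205 as deposited. A covariate for Y-linked expression or for the mean of the neutrophil, B and erythroid lists left 0 calls each by limma, with 2202 and 2341 genes at an unadjusted p under 0.05. The median size of the 578 log2 fold changes was 1.23 as reported and 1.09 and 1.17 with these covariates, and their median SE was 0.265, 0.329 and 0.362. Every named gene called here lost its call in at least 6 of the 8 fits that left out a library.

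The difference also followed transcript length. The median log2 fold change was 0.55 in the quartile of genes with the shortest transcripts (204 to 1962 bases) and -0.33 in the quartile with the longest (4614 to 106824 bases), and the Spearman correlation across genes, which are not independent replicates, was -0.63. Genes higher in CKO had a median transcript of 1091 bases, genes lower in CKO 6040.5 bases, and all tested genes 3086 bases. With the trend against length removed, an alternative added after the data were seen, limma called 0 of 12116 genes, with 2093 at an unadjusted p under 0.05. Among lists called by camera, those whose median moved by more than 1.5 times were the glycosaminoglycan enzymes (-0.36 to -0.20), YAP/TAZ targets (-0.53 to -0.32), the neutrophil lineage (1.28 to 0.63) and the B lineage (0.75 to 0.43).

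**Figure D2:**
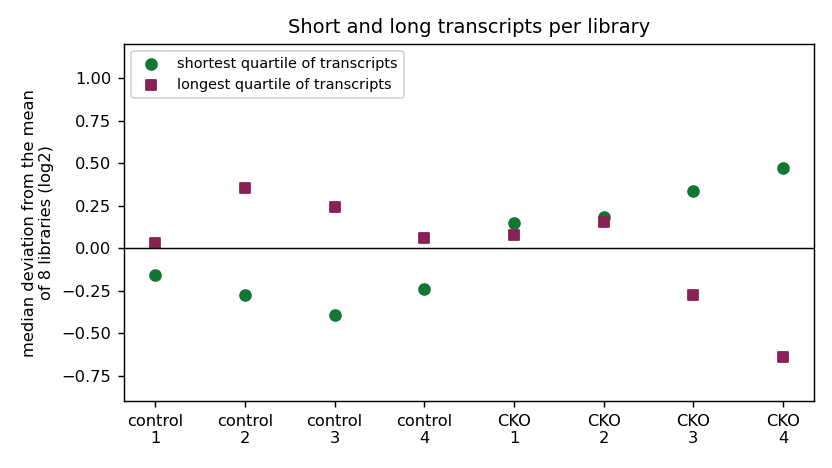
Median deviation of each library from the mean of all 8 libraries (log2), for the quartile of genes with the shortest transcripts (circles) and that with the longest (squares). Short transcripts lay below 0 in the 4 control libraries and above 0 in the 4 CKO libraries, and long transcripts lay lowest in CKO replicates 3 and 4.

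Some genes of osteoblast maturation were lower in CKO. Of 32 tested, 5 fell, none rose and 27 did not pass the threshold, and 9 fell when adjusted over the list alone. Ank, a transporter that exports pyrophosphate, fell from 118 ± 31.0 to 48.3 ± 14.9 FPKM (SD, n = 4; log2 fold change -1.28, limma adjusted p = 0.0388). Enpp1, which produces pyrophosphate, had a log2 fold change of -1.15, the membrane protease Mmp16 -0.98, and the homeobox factor Dlx3 -1.44. Other known genes of the list, chosen after their values were seen, did not pass over all genes. Of these, Runx2, Col1a1 and Col1a2 fell when adjusted over the list alone (limma adjusted p = 0.0133, 0.0470 and 0.0467). Runx2, a master regulator of osteoblasts, averaged 31.5 FPKM in control and 17.2 in CKO (adjusted p = 0.0512), Col1a1 15482 and 5880 FPKM (adjusted p = 0.102), and Col1a2 12267 and 5159 FPKM (adjusted p = 0.0963). Ibsp had 321 and 312 FPKM, and the late marker Bglap, which has near-identical copies, 3660 ± 2014 and 4708 ± 5221 FPKM (adjusted p = 0.836 and 0.940). The CKO mean of Bglap rested on replicate 4, at 12420 FPKM against 1210 to 3375 FPKM in the other CKO libraries. The list was called lower by camera (adjusted p = 1.26e-06, and adjusted p = 0.432 with an estimated correlation), with a median log2 fold change of -0.63. That call ended with the marrow covariate (adjusted p = 0.0776, median -0.33).

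Among 15 osteocyte genes 1 fell, Ptprz1, a receptor phosphatase (log2 fold change -1.20, limma adjusted p = 0.0495), 14 did not pass, and 1 fell when adjusted over the list alone. Dmp1, chosen after its values were seen, averaged 389 ± 158 FPKM in control and 236 ± 93.9 in CKO (SD, n = 4; adjusted p = 0.299). Of 25 genes of skeletal progenitors, periosteum and fibroblasts 1 fell, the transcription factor Foxc1 (log2 fold change -1.04), 24 did not pass, and 2 fell when adjusted over the list alone. Both lists were called lower by camera (adjusted p = 0.000152 and 0.0318, and adjusted p = 0.432 and 0.514 with an estimated correlation). The progenitor call ended with the marrow covariate (adjusted p = 0.937), the Y-linked covariate (0.340) and equal FPKM totals (0.0973), and without control replicate 3, control replicate 4 or CKO replicate 2 (adjusted p = 0.117, 0.178 and 0.0715).

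Few single genes of the matrix passed the threshold. Of 46 collagen and collagen-processing genes, 3 fell, 43 did not pass, and 8 fell when adjusted over the list alone. The 3 were the crosslinking oxidases Loxl2 (30.2 ± 5.83 to 12.7 ± 2.92 FPKM, SD, n = 4; log2 fold change -1.20) and Loxl4 (-1.01) and the procollagen protease Adamts2 (-1.07). None of 28 proteoglycan core protein genes passed, over all genes or over the list alone, although 26 had a log2 fold change below 0. Bgn averaged 703 ± 159 FPKM in control and 350 ± 152 in CKO (limma adjusted p = 0.0860), and Dcn 418 ± 65.8 and 296 ± 48.3 (adjusted p = 0.213). None of 37 enzymes of glycosaminoglycan synthesis and sulfation passed on either count, with 32 below 0. B3gat3 had a log2 fold change of 0.31 and Ext2 of -0.33. Of 30 matrix proteases and inhibitors 1 fell, Mmp16, 29 did not pass, and 4 fell when adjusted over the list alone. These 4 lists were called lower by camera, in the order given, at adjusted p = 3.70e-08, 6.71e-06, 2.31e-05 and 0.000184, and with an estimated correlation at adjusted p = 0.432 each. The marrow covariate ended the calls of the collagen and proteoglycan lists (adjusted p = 0.0882 and 0.0674), whose medians went from -0.54 each to -0.26 and -0.36. Of 10 sulfate uptake and activation genes 1 fell, Slc26a2, on either count, and the list was not called (adjusted p = 0.287, and adjusted p = 0.527 with an estimated correlation).

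A few genes of adhesion and mechanosensing differed. Of 40 in the focal adhesion and mechanosensing list 2 fell and 38 did not pass, and adjusted over the list alone 5 fell and 1 rose. Kank1, a regulator of focal adhesions, fell from 10.7 ± 0.710 to 4.06 ± 1.22 FPKM (SD, n = 4; log2 fold change -1.24, limma adjusted p = 0.0388), and Itga11, a collagen-binding integrin, had a log2 fold change of -1.10. Piezo1, a mechanically gated channel chosen after its values were seen, averaged 31.0 FPKM in control and 15.6 in CKO. Its limma adjusted p was 0.0584 over all genes and 0.0272 over the list alone. Of 26 YAP/TAZ target genes 2 fell, Ccn2 (log2 fold change -0.95) and Ptpn14 (-0.96), 1 rose, the growth arrest gene Gadd45a (1.21), and 23 did not pass. Adjusted over the list alone, 7 fell and 1 rose. Both lists were called lower by camera (adjusted p = 2.94e-07 and 6.71e-06, and adjusted p = 0.432 each with an estimated correlation).

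Among signalling genes 2 passed the threshold. Of 18 Wnt pathway targets and inhibitors 1 fell, Notum, a secreted Wnt inhibitor (20.3 ± 6.65 to 7.76 ± 3.10 FPKM, SD, n = 4; log2 fold change -1.29), 17 did not pass, and 2 fell when adjusted over the list alone. Of 22 BMP and TGF-beta response genes 1 fell, Bmp8a (log2 fold change -1.41), 21 did not pass, and 6 fell when adjusted over the list alone. None of 16 Hedgehog and FGF feedback genes passed on either count. Fgfr1 averaged 110 ± 27.5 FPKM in control and 51.7 ± 17.3 in CKO (limma adjusted p = 0.0673), and Fgfr2 54.6 and 33.9 (adjusted p = 0.126). By camera the 3 lists were called lower (adjusted p = 0.000902, 0.000902 and 0.000114). With an estimated correlation the values were adjusted p = 0.481, 0.432 and 0.432. The medians were -0.46, -0.32 and -0.64. All 3 calls ended with the marrow covariate (adjusted p = 0.130, 0.0755 and 0.117), where the medians were -0.40, -0.52 and -0.53, and the Wnt and Hedgehog calls also with the Y-linked covariate (0.134 and 0.0818).

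Some markers of marrow lineages were higher in CKO. Of 21 neutrophil lineage genes 5 rose, none fell, 16 did not pass, and 10 rose when adjusted over the list alone. The 5 were Camp, S100a8, S100a9, Stfa2l1 and Wfdc21, and S100a8 went from 633 ± 338 to 4592 ± 4225 FPKM (SD, n = 4; log2 fold change 2.72, limma adjusted p = 0.0474), with 10823 FPKM in CKO replicate 3 alone. Of 21 erythroid genes 4 rose, 17 did not pass, and 5 rose when adjusted over the list alone. They were the alpha globin copies Hba-a1 (log2 fold change 2.26) and Hba-a2 (2.20), which share near-identical sequence and are uncertain apart, the blood group gene Rhd (1.44) and, chosen after its values were seen, the heme synthesis enzyme Alas2 (1.72). Of 13 megakaryocyte and platelet genes 2 rose, Pf4 (log2 fold change 2.38) and Gp1bb (2.45), 11 did not pass, and 5 rose when adjusted over the list alone. None of 19 B lineage genes passed on either count, and Igll1 averaged 31.0 ± 17.4 and 77.9 ± 36.1 FPKM and Cd79b 37.4 ± 34.3 and 69.2 ± 30.1. These 4 lists were called higher by camera, in the order given, at adjusted p = 4.22e-07, 9.17e-05, 0.0240 and 0.0203, and with an estimated correlation at adjusted p = 0.432, 0.481, 0.527 and 0.635. With the marrow covariate, which is built from 3 of them, all 4 calls ended (adjusted p = 0.113, 0.796, 0.937 and 0.0882). The Y-linked covariate ended the last 3 (0.0502, 0.215 and 0.245), and array weights ended the neutrophil call (0.0669).

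The B lineage and platelet calls depended on single libraries and on the filter, with an adjusted p of 0.0763 and 0.0990 at 5 FPKM. There the medians were 0.78 and 1.61, against 0.75 and 0.56 as reported. Without control replicate 4, CKO replicate 1, CKO replicate 2 or CKO replicate 4, the B lineage adjusted p by camera was 0.245, 0.0986, 0.0715 and 0.0763. The B lineage medians there were 0.32, 0.46, 0.64 and 0.84. Within the libraries lacking Y-linked expression, with a single control, the B lineage median log2 fold change was -0.56. Without control replicate 4, CKO replicate 1 or CKO replicate 4, the platelet adjusted p was 0.0959, 0.0788 and 0.0746, and the platelet median was 0.09, 0.17 and 1.37.

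Markers of other cell types of the shaft mostly did not pass. None of 19 endothelial genes passed over all genes, and 9 fell when adjusted over the list alone. Plvap averaged 88.6 ± 16.1 FPKM in control and 59.7 ± 26.2 in CKO, and Egfl7 76.9 ± 11.8 and 129 ± 76.8 (SD, n = 4). Of 20 osteoclast genes 1 fell, the myosin Myo1d (log2 fold change -1.23), 19 did not pass, and 2 fell when adjusted over the list alone. Both lists were called lower by camera (adjusted p = 6.82e-05 and 0.000902, and adjusted p = 0.432 and 0.481 with an estimated correlation). The osteoclast call ended with the marrow covariate (0.304) and with the Y-linked covariate (0.134). All 26 skeletal muscle genes had a log2 fold change above 0 and none passed on either count. Acta1 averaged 427 ± 518 FPKM in control and 1184 ± 1491 in CKO, and Mylpf 157 ± 192 and 485 ± 432. The muscle list was called higher by camera (adjusted p = 0.0129, and adjusted p = 0.662 with an estimated correlation), and this call ended with the filter at 5 FPKM (0.0686), with array weights (0.184), and without control replicate 1, control replicate 2 or CKO replicate 4 (adjusted p = 0.269, 0.133 and 0.705).

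**Figure D3:**
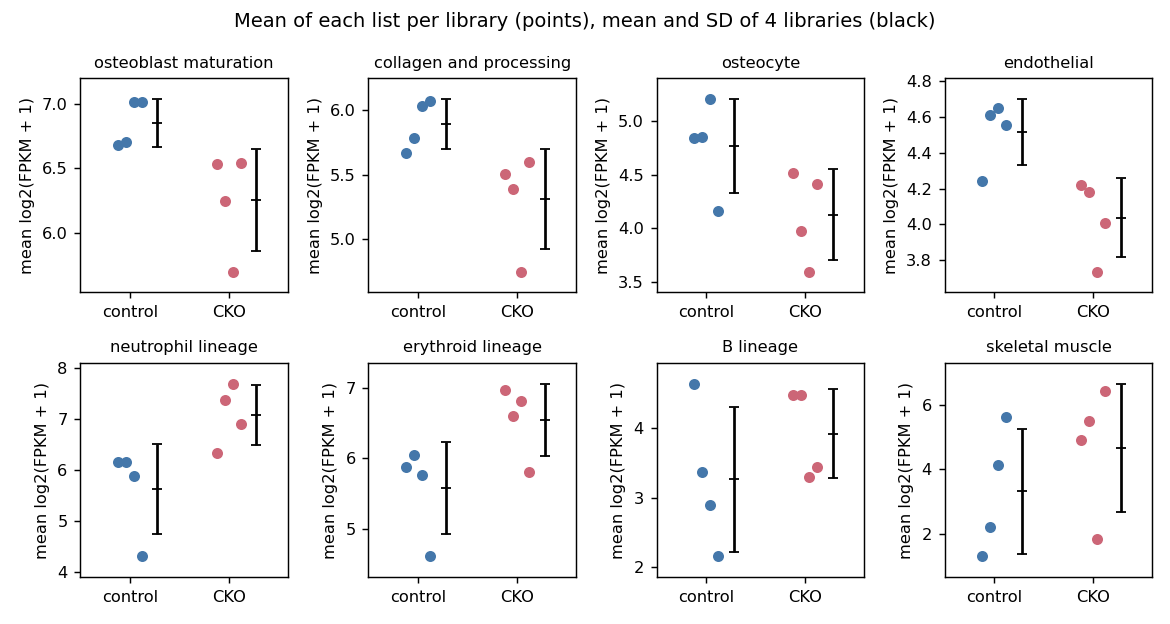
Mean log2(FPKM + 1) of 8 gene lists in each library (points, control blue, CKO red), with the mean and SD of 4 libraries in black and axes that do not start at 0. The neutrophil list was lowest in control replicate 4 at 4.31, and the muscle list ranged from 1.31 to 6.43 across libraries.

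Several lists of other cell types and of regulators were not called with all 8 libraries. None of 17 monocyte and macrophage genes, 2 T and NK genes, 6 adipocyte genes, 8 chondrocyte genes and 7 osteoclast-regulating cytokines passed over all genes or over the list alone. Lyz2 averaged 253 ± 138 and 536 ± 341 FPKM, Ly6c2 80.9 and 159, Nkg7 8.33 and 14.9, Cd4 1.32 and 1.88, Car3 222 and 207, Fabp4 117 and 238, Col2a1 39.8 and 45.9, Fgfr3 16.9 and 10.6, Cxcl12 440 and 451, and Csf1 26 and 20.7, each as control and CKO means of 4 libraries. The camera adjusted p of the 5 lists was 0.352, 0.287, 0.385, 0.104 and 0.103, and with an estimated correlation it was 0.727, 0.514, 0.567, 0.527 and 0.481. The median of the monocyte list (0.33) and of the adipocyte list (0.19) turned below 0 when libraries were rescaled to equal FPKM totals, which moved the median of all genes to -0.37, and relative to that shift no list changed sign. The chondrocyte list was called lower without control replicate 1 or CKO replicate 1 (adjusted p = 0.0471 and 0.0499) and with the muscle covariate (0.0168), and the cytokine list without control replicate 2 (adjusted p = 0.0458) and with the Y-linked covariate (0.0396). The monocyte list was called higher with the muscle covariate (adjusted p = 0.0328) and lower within the libraries without Y-linked expression (0.0285), which hold a single control.

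Some cell division genes were higher in CKO. Of 29 tested 5 rose, none fell, 24 did not pass, and 9 rose when adjusted over the list alone. Birc5, a mitotic survivin, rose from 29.6 ± 10.7 to 92.2 ± 15.4 FPKM (SD, n = 4; log2 fold change 1.65, limma adjusted p = 0.0388), and Ube2c and Ccne1 had log2 fold changes of 1.18 and 1.12. The other called members, Tyms (1.16) and Cdk1 (0.97), were chosen after their values were seen. None of 11 interferon response genes passed over all genes, and 4 rose when adjusted over the list alone. Bst2 averaged 21.4 ± 9.81 and 51.0 ± 20.2 FPKM and Isg15 3.03 ± 3.68 and 10.1 ± 2.82. Both lists were called higher by camera (adjusted p = 8.35e-06 and 0.00352, and adjusted p = 0.514 and 0.432 with an estimated correlation). With the marrow covariate both calls ended (adjusted p = 0.937 and 0.376), and the median of the cell division list turned to -0.18. Both calls also ended with the Y-linked covariate (adjusted p = 0.262 and 0.271), where the medians were 0.10 and 0.32 against 0.61 and 0.62 as reported. The interferon call ended with the filter at 5 FPKM too (0.199), where its median was 0.98.

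Stress and metabolic lists were not called. Of 21 immediate early and heat shock genes 1 fell, Egr3 (log2 fold change -1.17, limma adjusted p = 0.0497), and 3 fell when adjusted over the list alone (list camera adjusted p = 0.197, and adjusted p = 0.560 with an estimated correlation). This list was called lower with the length trend removed (adjusted p = 0.0209), with the Y-linked covariate (adjusted p = 0.0298), and within the libraries without Y-linked expression, which hold a single control (adjusted p = 0.00897). None of 28 unfolded protein response genes passed over all genes, and 2 rose when adjusted over the list alone (list camera adjusted p = 0.522, and adjusted p = 0.782 with an estimated correlation). Calr averaged 179 and 208 FPKM and Pdia3 117 and 148 in control and CKO. Of 26 glycolysis and hypoxia genes 1 rose, the mitochondrial protein Higd1a (log2 fold change 1.04), on either count (list camera adjusted p = 0.366, and adjusted p = 0.689 with an estimated correlation). The medians of these last lists, 0.15 and 0.18, turned below 0 with quantile normalization and with equal FPKM totals. None of 25 cholesterol and fatty acid synthesis genes and 13 mitochondrially encoded genes passed on either count, and their camera adjusted p was 0.333 and 0.366, or 0.689 and 0.757 with an estimated correlation. Acly averaged 24.5 and 21.1 FPKM, Scd2 27.0 and 18.1, mt-Co1 10005 and 9365, and mt-Atp6 4630 and 5857. In CKO replicate 3 mt-Atp6 stood at 12105 FPKM, against 1610 to 5126 FPKM in the other CKO libraries. The mitochondrially encoded list was called lower without CKO replicate 3 (adjusted p = 0.0301), with the length trend removed (0.000113), with the Y-linked covariate (0.0396) and within the libraries with Y-linked expression, which hold a single CKO library (0.0211). Without CKO replicate 4 its median was 0.32. None of 5 sex-linked genes passed on either count (list camera adjusted p = 0.262, and adjusted p = 0.481 with an estimated correlation), and without a filter the list was called lower (0.0347). Eif2s3x averaged 35.4 and 55.0 FPKM and Kdm6a 7.98 and 10.6.

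**Figure D4:**
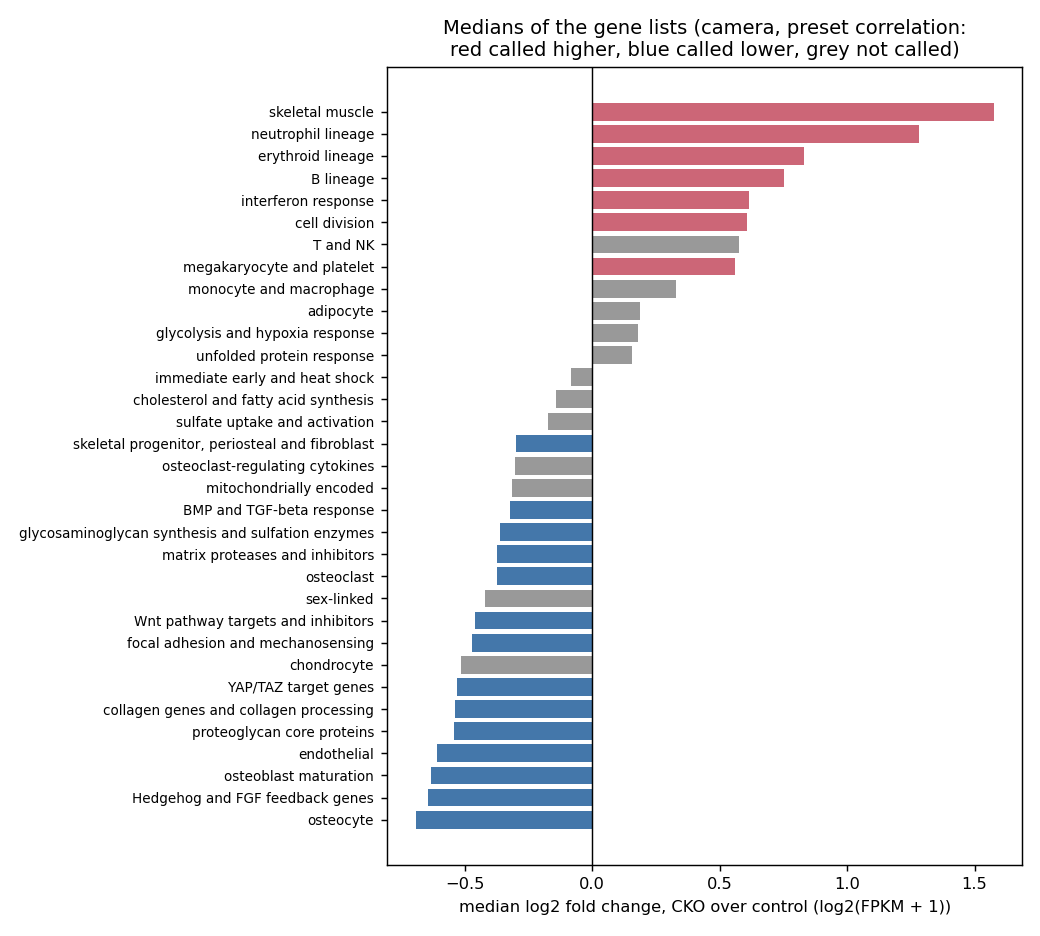
Median log2 fold change (CKO over control, log2(FPKM + 1)) of the 33 gene lists. Bars are red where camera with the preset correlation called a list higher, blue where it called it lower and grey where it did not, and the medians ran from -0.69 for osteocyte genes to 1.57 for skeletal muscle genes.

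Over all lists, camera with the preset correlation called 21 of 33, 7 higher and 14 lower. With an estimated correlation it called 0, with adjusted p between 0.432 and 0.782, and fry called 0, with a lowest adjusted p of 0.107. With the marrow covariate 7 lists were called.

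Fits within the Y-linked classes each rest on a group of 1 library, which limma assumes to vary like the others. Control replicate 1 is the only control without Y-linked expression, and CKO replicate 4 the only CKO library with it. Without Y-linked expression 18 lists were called. The calls of the progenitor (median 0.14, adjusted p = 0.657), osteoclast (-0.01, 0.359), platelet (0.68, 0.0561), Hedgehog and FGF (-0.16, 0.123) and interferon (0.19, 0.605) lists ended there, against medians of -0.30, -0.37, 0.56, -0.64 and 0.62 with all libraries. With Y-linked expression 9 were called, and 13 calls ended. Those were the osteoblast (median -0.64, adjusted p = 0.292), osteocyte (-0.05, 0.659), progenitor (-0.67, 0.273), collagen (-0.46, 0.292), protease (-0.59, 0.0981), osteoclast (-0.75, 0.104) and endothelial (-0.72, 0.140) lists. The erythroid (-0.30, 0.419), platelet (0.46, 0.273), cell division (-0.06, 0.370), Wnt (-0.61, 0.0981), BMP and TGF-beta (-0.81, 0.158) and interferon (0.68, 0.0981) calls ended there too. With all libraries the medians of these 13 lists were, in the same order, -0.63, -0.69, -0.30, -0.54, -0.37, -0.37, -0.61, 0.83, 0.56, 0.61, -0.46, -0.32 and 0.62.

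In the authors' deposited table, 4070 of 14457 genes had a p-value under 0.05, 2339 higher and 1731 lower in CKO. A Benjamini-Hochberg adjustment of the p-values in the authors' deposited table left 2030 genes, 1214 higher and 816 lower, among them 574 of the 578 genes called here by limma. For Slc26a2 the authors' deposited table gives a log2 fold change of -1.53 and a p-value of 5.33e-06.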

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

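The tests of the split by Y-linked expression, of CKO replicate 4 and of the share of osteoblasts were chosen after the results were seen. So was the test of the genotype difference by Y-linked class. The test of other splits of the libraries was planned, but the rule for reading it was written after the count was seen. The other tests below were written down before their result was seen.

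The first pattern is the number of genes that differed. The real split of the 8 libraries gave 578, and the highest of the other 34 of 35 splits gave 47. Only 1 split, the real one, gave as many, the fewest that 35 splits can give. The rule for reading this test was written after the count was seen, so it argues against chance for these libraries but cannot exclude it. The split by Y-linked expression, control replicate 1 with CKO replicates 1 to 3 against the rest, gave 33 genes, but 2642 at an unadjusted p under 0.05 against 3228 by genotype. With the Y-linked covariate limma called 0 genes, with 2202 at an unadjusted p under 0.05, and the median size of the 578 log2 fold changes went from 1.23 to 1.09 while their median SE went from 0.265 to 0.329. Unequal sex cannot be told apart from genotype for the count, since 3 of 4 libraries in each genotype share their Y-linked class. The difference in Slc26a2 that the design names, and any difference between litters or preparations, stay open.

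The second pattern is that short transcripts were higher and long transcripts lower in CKO. With the marrow covariate the Spearman correlation of the log2 fold change with transcript length was -0.65, so the covariate did not remove the trend. That covariate shares its variation with genotype over these libraries, so retained marrow is not excluded. CKO replicate 4 alone is argued against, since without it the correlation was -0.51. A length-dependent difference between libraries that acts on all genes is a candidate explanation: among genes outside the fixed lists, ribosomal proteins and respiratory chain genes, the correlation lay between -0.68 and -0.52 in every quartile of mean expression. Removing the trend took the median size of the called log2 fold changes from 1.23 to 0.63 while their median SE went from 0.265 to 0.219, so the calls ended because the differences shrank. Of 545 called genes tested, 526 kept their sign, and 333 kept it with an unadjusted p under 0.05 by limma. These genes were selected from the same libraries, so kept signs are not independent support. A change in transcript lengths that follows genotype stays open.

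The third pattern is that lists of osteoblast and matrix genes were called lower and lists of blood lineage genes higher in CKO by camera with a preset correlation. With an estimated correlation camera called 0 lists, and fry called 0. A lower share of osteoblasts alone would raise both the neutrophil and the endothelial list mean. The neutrophil mean minus the endothelial mean was higher by 1.93 log2 units in CKO (exact permutation p = 0.0286, the smallest that 70 assignments can give). The endothelial mean itself was lower in CKO, with a difference of -0.48 (SE 0.14). The 2 lists were chosen after their opposite shifts were seen, so the permutation test cannot decide on that explanation. They also differ in median transcript length, at 1025 and 3974 bases. With the length trend removed their medians were 0.63 and -0.48, still of opposite sign, and the permutation test was not repeated. Retained marrow cannot be told apart from the genotype for the osteoblast list. Its mean differed by -0.60 (SE 0.22) and, with the marrow covariate, by -0.36 (SE 0.30). The estimate with the covariate, plus or minus its SE, reaches from -0.65 to -0.06. That range is not a confidence interval, so it does not show that the list stayed lower with the covariate. The marrow mean itself was higher by 1.04 (SE 0.43) in CKO, so the 2 terms share their variation over 8 libraries. A loss of osteoblast gene expression that follows Slc26a2 stays open with it.

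By Dixon's test a library lay far from the other 3 of its group in 23 of 272 groups of 4 values tested, where chance gives about 1 in 20, or 13.6. For Cxcl12 this holds at the tabulated critical value of 0.829 and not at the value before truncation, 0.82975. In CKO replicate 4 these were 155 genes listed at 0, Cxcl12 at 195 FPKM, Egfl7 at 243 FPKM, Eif2s3x at 14.6 FPKM, Kdm6a at 2.44 FPKM, Cdk1 at 15.5 FPKM and the cell division list mean at 3.99 log2 units. In CKO replicate 3 they were Adamts2 at 15 FPKM, Car12 at 0.462 FPKM, Col2a1 at 11.9 FPKM and Egr3 at 1.59 FPKM. In control replicate 1 they were Ext2 at 31.4 FPKM, Foxc1 at 11 FPKM, Plvap at 64.7 FPKM, Ptpn14 at 5.06 FPKM, Runx2 at 23.0 FPKM and the means of the unfolded protein response (4.67), Hedgehog and FGF feedback (2.81) and immediate early (3.99) lists. In control replicate 4 they were Egfl7 at 94.5 FPKM, Hba-a2 at 832 FPKM, Alas2 at 16.6 FPKM and the neutrophil list mean at 4.31 log2 units.

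A limma interaction term of genotype with Y-linked class passed the threshold for 1446 of 12748 genes (Benjamini-Hochberg), 41 of them among the 578. It rests on control replicate 1 and CKO replicate 4, each the only library of its genotype and class, and assumes that they vary like the others. It therefore cannot separate a difference by Y-linked class from what is particular to these 2 libraries, of which CKO replicate 4 stands apart in other measures. Among the named genes, the log2 fold change without minus that with Y-linked expression was -2.03 for Bst2, 1.49 for Eif2s3x, 1.8 for Kdm6a and -3.997 for Bglap. For Slc26a2 the interaction was not past the threshold (unadjusted p = 0.200).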

How the results depend on the processing

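Fits with equal FPKM totals, with the length trend removed and within Y-linked classes were chosen after the data were seen, and the others were planned. Of the named genes' fits under all alternatives, 1369 gave the same direction and side of the threshold as the reported value, 806 lost the call, 80 gained one, 65 changed sign without a call in either fit and 5 changed sign with a call in at least 1. For the lists, where the sign is the direction given by camera and not that of the median, the numbers were 698, 57, 14, 15 and 7. The list numbers cover only fits of camera with the preset correlation. They leave out camera with an estimated correlation and fry, each of which called 0 lists. The cause of the changes below was not tested except where stated. Depth is unknown, so what it limits could not be assessed. The count models planned as an alternative were not run, since whole reads were not recovered, and the filter at 5 FPKM left out Slc26a2.

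Genes differing, higher, lower and differing at least 2-fold (578, 495, 83 and 452 as reported) numbered 0, 0, 0 and 0 with median-of-ratios scaling, the Y-linked covariate, the marrow covariate, equal FPKM totals and the length trend removed, by limma, with 3397, 2202, 2341, 3934 and 2093 genes at an unadjusted p under 0.05. They numbered 358, 137, 221 and 257 with quantile normalization, 6005, 4104, 1901 and 953 with array weights, and 1614, 1168, 446 and 1013 with the skeletal muscle covariate. Without a filter 381 differed, 327 higher and 54 lower, with more genes tested. The filter at 5 FPKM gave 132 lower and the pseudocount of 0.01 gave 53 lower. Within the libraries without Y-linked expression they numbered 1, 1, 0 and 1, and within those with it 6095, 2349, 3746 and 3900, where the lone library of a group is assumed to vary like the others. Leaving out 1 library gave 0 to 1885 genes differing, 0 to 1535 higher, 0 to 350 lower and 0 to 699 at least 2-fold.

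The log2 fold change of Slc26a2 kept its sign under every alternative that tested it. It was -1.35 (limma adjusted p = 0.0638) with median-of-ratios scaling, -1.93 (0.0514) with a pseudocount of 0.01, -1.35 (0.219) with the Y-linked covariate, -1.52 (0.202) with the marrow covariate, -1.65 (0.0637) with equal FPKM totals, -0.96 (0.113) with the length trend removed, -0.80 (0.00377) with array weights, -0.97 (0.731) within the libraries without Y-linked expression, and between -1.56 and -1.16 with 1 library left out. Its adjusted p over all alternatives lay between 0.00377 and 0.731.

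Lists called by camera (21 as reported) numbered 7 with the marrow covariate, 9 within the libraries with Y-linked expression, 0 with an estimated correlation, 0 by fry, and 18 to 22 with 1 library left out.

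With replicate number as a block, 274 genes differed, 249 higher and 25 lower, 268 of them at least 2-fold. The deviations of same-numbered libraries correlated at -0.03, 0.23, -0.26 and 0.43. These values do not show that the numbers pair the libraries, and they cannot exclude it.

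Reversed values were the B lineage median at -0.27 with the Y-linked covariate, -0.39 with the marrow covariate and -0.56 within the libraries without Y-linked expression, where it was called lower against a single control (adjusted p = 2.14e-05), the monocyte median at -0.14 within those libraries, and the skeletal muscle median at -0.11 with its own covariate, by construction. With the marrow covariate the megakaryocyte and platelet median was -0.39 and the cell division median -0.18, and the erythroid median, which lost its call, was -0.24. The skeletal progenitor median was 0.14 within the libraries without Y-linked expression, and the erythroid and cell division medians -0.30 and -0.06 within those with it, none of them called. Cxcl12 was 0.44 with array weights. Within the libraries with Y-linked expression, Eif2s3x was -1.03, Kdm6a -1.29, mt-Atp6 -1.52 and Bglap 2.23.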

Other observations

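Both gene families below were noticed in the data, and the tests of their medians were written down before the result was seen, while the comparison library by library was chosen after it. The first holds ligands and receptors of axon guidance, with roles in bone and vessels as well as nerve. Of 55 tested, 9 fell by limma with Benjamini-Hochberg adjustment, none rose, 46 did not pass, and 47 had a log2 fold change below 0. The 9, chosen after their values were seen except Unc5c, were the secreted ligands Slit2 (log2 fold change -1.12) and Slit3 (-1.33), the semaphorins Sema5a (-1.31) and Sema6d (-1.27), and the receptors Unc5c (-1.36), Plxna1 (-1.19), Neo1 (-1.17), Nrp2 (-0.92) and Boc (-1.24). Slit3 averaged 42.5 ± 10.2 FPKM in control and 16.9 ± 6.32 in CKO, and Nrp2 89.2 ± 4.61 and 47.7 ± 12 (SD, n = 4). The family's median was below 0 under each scaling tried, between -0.94 with equal FPKM totals and -0.53 with median-of-ratios scaling.

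The second family holds genes of cytosolic ribosomal proteins. Of 76 tested, 30 rose in CKO, none fell, 46 did not pass, and all had a log2 fold change above 0. Their median was 1.34, and it stayed above 0 under each scaling tried, at 1.35 with median-of-ratios scaling, 0.38 with quantile normalization and 0.86 with equal FPKM totals. Many of these genes have near-identical pseudogene copies, so single values are uncertain.

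Both families have unusual transcript lengths, with medians of 4793 and 925.5 bases, so the length trend may account for their shifts. Of all genes in the quartile with the longest transcripts, 17.8% had a log2 fold change above 0, and of those in the shortest quartile 87.1%. The median of the guidance family was -0.54, while 95% of 10000 random lists matched on transcript length and mean expression had medians between -0.33 and -0.11. The ribosomal median of 1.34 lay above the matched range of 0.80 to 1.08. These ranges are too narrow to exclude length, since random lists hold unrelated genes while the members of the families vary together (estimated correlation 0.35 and 0.69), and the families were picked for their shift. Compared library by library, the mean of the guidance family minus that of its matched genes differed by -0.37 (SE 0.13) between CKO and control, and that of the ribosomal family by 0.44 (SE 0.18), each with an exact permutation p of 0.0571. Length therefore cannot be told apart from genotype for either shift. With the length trend removed the medians were -0.36 and 0.41, and with the marrow covariate they were -0.45 and 1.42. Within the libraries without and with Y-linked expression the guidance median was -0.16 and -0.77, and the ribosomal median 0.81 and 1.91.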
